A study of Mus musculus with 12 samples.

How the data were processed

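RNA-seq of colon tissue from 12 mice was used, 6 with an intestinal epithelial deletion of Pck1 and 6 littermate controls, all given 2.5% DSS for 7 days. Per the labels' protocols, total RNA was taken from the tissue with Trizol and libraries were made with the SMARTER mRNA-Seq kit. Groups and replicate numbers were taken from the labels, which number the mice 1 to 6 in each group. The authors deposited one table of the whole series with 21899 genes, which pairs Ensembl gene IDs with symbols, so symbols were taken from it. Per the file headers, the table holds whole-number read counts per gene and library, and the raw counts were used as deposited. Per the file headers, it also holds TPM per library, normalised by the authors for gene length and depth, and a mean TPM per group. The authors also deposited a log2 fold change, which equals the log2 ratio of the mean TPM values, and a p-value and adjusted p-value per gene, for which the labels name no test. The submitters' processing notes list the genome builds GRCm38, mm10 and mm39 without their roles, and the aligner, the counter and their versions are not given in the sources used here. Genes are therefore named by symbol and ID, without coordinates. Whether strand was used in counting is likewise not given, so values of overlapping genes and of near-identical copies (amylase, haemoglobin and immunoglobulin genes) are uncertain. The table held 0 columns of samples outside the series. Xist was not analysed here.

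Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15, groups of 6), which left 14393, and libraries were scaled by TMM. The main test was the quasi-likelihood F test (glmQLFit and glmQLFTest, without robust estimation) of knockout minus control over all 12 libraries with no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 0.262 and the prior degrees of freedom were 3.39. A log2 fold change is edgeR's, and its SE was derived from the fold change and the F statistic. CPM values are scaled by TMM, and their means and SDs are over 6 mice. Levels per library used log2 CPM with a prior count of 2.

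Before the data were examined, 39 gene lists were fixed, of which the list of sex genes served only as a check and 38 were tested. Of 594 list genes 588 were in the table, 1 of them matched by gene ID after a changed symbol. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, with fry, and by an exact two-sided permutation test of each list's mean log2 CPM per library over all 924 arrangements, each adjusted over the 38 lists. Camera called 14 lists higher and 13 lower at the preset correlation; no list kept its call with an estimated correlation, where the smallest adjusted p was 0.244, fry called 16, and the exact permutation test called 17. The estimated correlation widens the test by how far the members vary together between mice of one genotype. Members past the threshold were also counted adjusted over the list alone. Of all list members, only Pck1, Hmgcs1, Lss and Cx3cl1 passed over all tested genes.

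The genes to be named were fixed by rule before the data were examined: Pck1 and Pck2, the called genes with a symbol and a mean CPM of at least 1 in the higher group (at most 12 per direction, without predicted genes and receptor segments), the 5 with the smallest p per direction where fewer than 5 passed, and from each list up to 4 called members, or the 2 with the highest mean CPM where none was called. Further list members are named because they had the smallest p in their list or passed over the list alone, and were chosen after their values were seen. The same holds for Lgr5 and for genes named in other observations. Single values of some list members are not reported here.

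Alternatives were other scalings (DESeq2's size factors, library size only, upper quartile), no low-count filter or a mean CPM of at least 1, DESeq2 1.42.0, limma voom without and with sample quality weights, a surrogate variable (sva 3.50.0), the replicate number in the model, a log2 fold change of at least 1, and each library left out in turn. Chosen after seeing the data were the pancreas level as a covariate, a threshold of 0.1, robust quasi-likelihood, edgeR's likelihood ratio test, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), and the second component. All 12 libraries held reads of Y-linked genes (Ddx3y at no fewer than 251 counts), so no sex covariate was fitted. No libraries were alike within counting noise: the lowest chi-square per gene over the 66 library combinations was 19.6.

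Library totals of 15348192 to 19138507 counts set the counting error, and the most abundant gene, mt-Co1, took between 2.58% and 4.33% of a library. The procedures were tested on simulated data with 14393 genes drawn from the means and library sizes of these samples, 200 of them changed. In this simulation of 6 against 6, edgeR called 74% of genes changed 2-fold and 97% of genes changed 4-fold with 15 unchanged genes, and DESeq2 called 81% and 100% with 52 unchanged genes. The exact list test was tried on the measured log2 CPM with group means removed and libraries shuffled, and was under 0.05 for 4.5% of unshifted lists. Shuffling fixes that share near the threshold, so it checks only the calculation. Figures were drawn with matplotlib 3.10.9.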

Results

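Colon RNA was sequenced from 12 mice that had been given 2.5% dextran sulfate sodium (DSS), a polymer that injures the colon lining and causes colitis, for 7 days. In 6 mice Pck1 had been deleted in the epithelial cells of the intestine, and 6 littermates served as controls. Pck1 encodes the cytosolic phosphoenolpyruvate carboxykinase, which turns oxaloacetate into phosphoenolpyruvate and is a rate-limiting enzyme of gluconeogenesis. Each library was made from whole colon tissue, so the values combine epithelium, immune cells, stroma and muscle. Total counts per library ranged from 15348192 to 18211663 in the 6 knockout libraries and from 15881625 to 19138507 in the 6 control libraries. Of 21899 genes, 18161 had at least 1 count and 14393 passed the low-count filter and were tested. The comparison asks how the colon transcriptome of DSS-treated mice differs when the epithelium lacks Pck1. No mice without DSS were used here, so each difference is between DSS-treated genotypes.

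Pck1 was lower in every knockout library than in any control library. Its level, as library-scaled counts (CPM), was 4.19 ± 2.10 CPM in the knockout and 53.0 ± 17.8 CPM in the control (SD, n = 6 each), or 7.91% of the control mean. The highest knockout library held 7.32 CPM and the lowest control library 34.5 CPM. Pck1 (ENSMUSG00000027513) fell by 3.66 on the log2 scale, with an SE of 0.32 and an edgeR adjusted p of 0.000391. An exact two-sided permutation test of its CPM gave p = 0.00216, the smallest that the 924 arrangements of 6 against 6 can give. Pck2, the mitochondrial form of the enzyme, stood at 29.2 ± 5.81 against 31.0 ± 6.55 CPM (knockout against control, SD, n = 6), a log2 fold change of -0.08 ± 0.16 (SE) and an edgeR adjusted p of 0.80.

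Besides Pck1, 3 genes fell and 4 rose in the knockout. Hmgcs1 (ENSMUSG00000093930), the HMG-CoA synthase of the cytosolic mevalonate route to cholesterol, fell from 449.6 ± 73.0 to 221 ± 23.3 CPM (SD, n = 6; log2 fold change -1.03 ± 0.12, SE). Lss (ENSMUSG00000033105), the lanosterol synthase of the same route, fell by 0.86, and Cx3cl1 (ENSMUSG00000031778), the chemokine fractalkine, fell by 0.59 on the log2 scale. Dio2 (ENSMUSG00000007682), the type 2 deiodinase that makes active thyroid hormone, rose by 2.66 and Zbtb16 (ENSMUSG00000066687), the transcription factor PLZF, by 2.24. Gpat3 (ENSMUSG00000029314), a glycerol-3-phosphate acyltransferase of triglyceride synthesis, rose by 0.75, and Pnrc1 (ENSMUSG00000040128), a nuclear receptor coactivator, by 0.55. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.00679 for Hmgcs1, 0.0407 for Cx3cl1, 0.0454 for Lss, 0.0407 for Zbtb16 and 0.0425 for each of Dio2, Gpat3 and Pnrc1. For all 8 genes each of the 6 knockout mice lay beyond all 6 controls. Such separation was seen for 219 of the tested genes (1.52%), where chance gives 0.216% on average. Genes vary together between mice, so a single grouping can lie far from that share, and separation was not counted in other splits. The 8 genes were called for their small p in the same libraries, so their separation is no separate evidence.

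**Figure D1:**
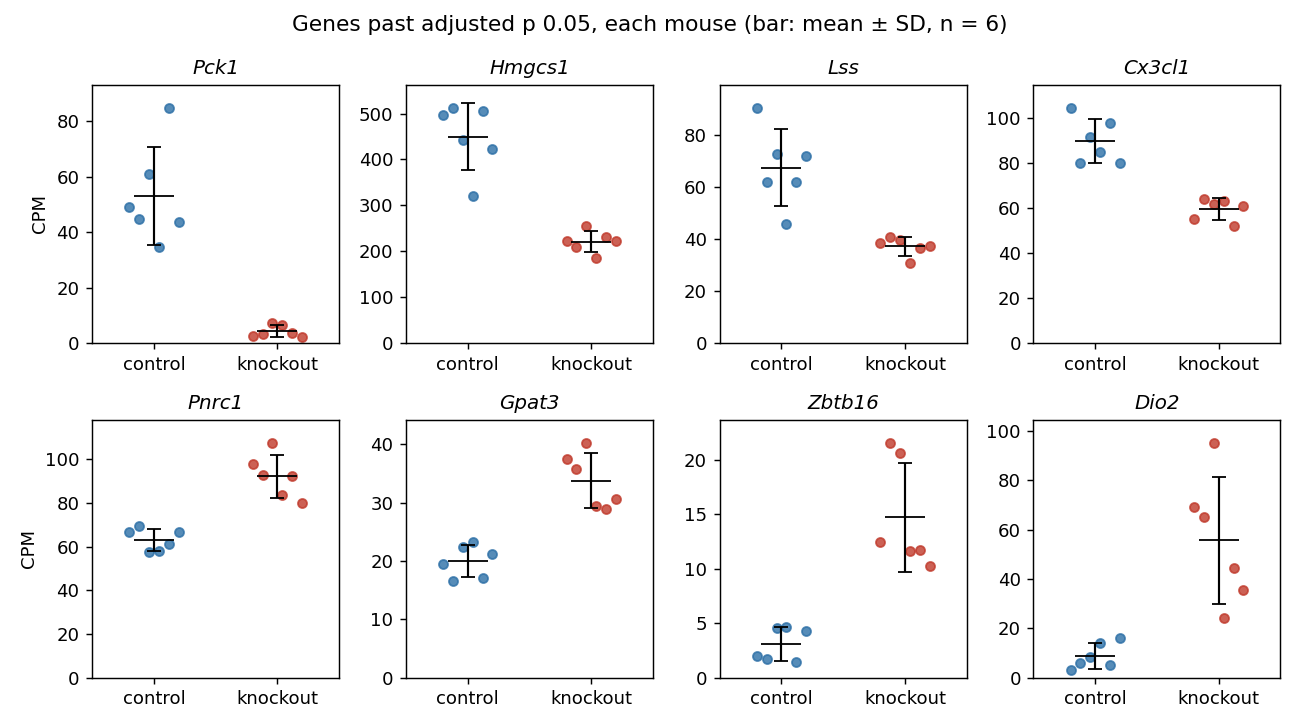
Level of the 8 genes past the threshold in each mouse, in CPM (vertical axis from 0) for control (blue) and knockout (red), with bars for the mean and SD of 6 mice. The groups do not overlap for any of the 8 genes; Pck1 lies between 2.28 and 7.32 CPM in the knockout and between 34.5 and 84.7 CPM in the control.

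The 5 genes with the next smallest p in each direction missed the threshold narrowly, at an edgeR adjusted p of 0.0512. On the lower side these were Insig1 (-0.95 ± 0.17), Id1 (-0.90 ± 0.16), Aacs (-0.83 ± 0.15), Mmab (-0.74 ± 0.13) and Pcyt2 (-0.66 ± 0.11), given as log2 fold change and SE. Insig1 encodes a protein that restrains sterol synthesis, and Aacs activates acetoacetate for lipid synthesis. On the higher side these were Hmox1 (1.97 ± 0.33), the haem-degrading stress enzyme, Mmp19 (1.59 ± 0.29), Nfil3 (1.55 ± 0.26), Adamts9 (1.52 ± 0.28) and Itgb3 (1.21 ± 0.22). At an unadjusted p under 0.05 there were 3250 genes, 22.6% of those tested, with 1885 higher and 1365 lower. Chance gives 5% on average, but genes vary together between mice, so a single grouping can lie far from it. In 99 other splits of the same libraries the count ran from 75 to 4273. The highest split exchanged knockout replicate 4 and control replicate 4, and the next highest held 3021. The other splits carry genotype differences within or between their groups, so they set no exact chance level. The adjusted p values crowded just above the threshold: 380 genes were under 0.06, and 949 higher and 435 lower genes were under 0.1.

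The number of genes called depended strongly on the test and on single libraries. With library size as the only scaling the same fit called 230 higher and 45 lower genes, and with DESeq2's size factors 33 and 19, in place of 4 and 4. DESeq2's own test called 1095 higher and 416 lower genes. Without knockout replicate 4 the quasi-likelihood test called 870 higher and 402 lower genes, without control replicate 4 it called 728 and 279, and without control replicate 6 it called 272 and 101. Leaving out any other library gave 0 higher and 2 or 3 lower genes in edgeR, with 2536 to 3093 genes at an unadjusted p under 0.05, and of the 8 calls kept only Pck1 and Hmgcs1. Pck1 passed under every setting tried.

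Genes of lipid and sterol synthesis were lower in the knockout as a group. All 16 measured members had a negative log2 fold change, with a median of -0.64; Hmgcs1 and Lss fell over all genes tested, and 14 of 16 were lower when adjusted over the list alone. Besides Hmgcs1 and Lss, the smallest p belonged to Sqle (-0.73 ± 0.14, SE), the squalene epoxidase, and Idi1 (-0.89 ± 0.17), an isomerase of the mevalonate route. Fatty acid enzymes were in the group too, among them Acly (-0.68 ± 0.17) and Fasn (-0.63 ± 0.16). The camera test gave the list an adjusted p of 8.87e-12, and adjusted p = 0.244 with an estimated correlation. The mean log2 CPM of the list per library was 0.63 lower in the knockout (SDs 0.16 and 0.25, n = 6 each; exact permutation p = 0.00216, adjusted 0.0206), with no overlap between the groups. Control replicate 4 lay nearest to the knockout, at -0.09 from the mean of all 12 libraries, while the other controls lay between 0.19 and 0.68 and the knockouts between -0.56 and -0.11.

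**Figure D2:**
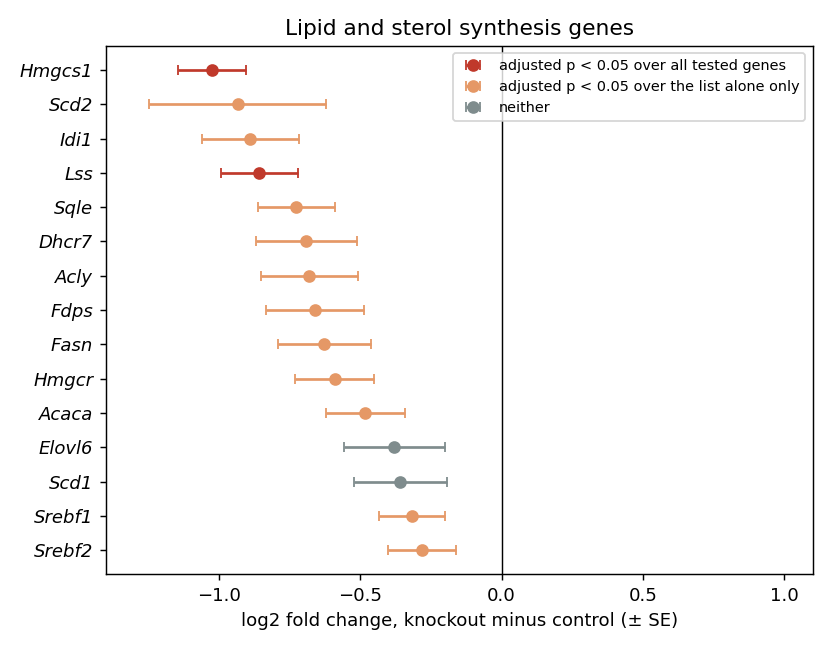
Log2 fold change (knockout minus control, horizontal axis) with its SE for 15 of the 16 measured lipid and sterol synthesis genes, from 6 mice per group. All plotted values lie below 0, from -1.03 for Hmgcs1 to -0.28 for Srebf2, and colour marks genes past an adjusted p of 0.05 over all tested genes, over the list alone only, or neither.

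Other metabolic lists moved less. The TCA cycle list was below 0 in 16 of 16 members (median -0.20; camera adjusted p = 2.96e-05, adjusted p = 0.263 with an estimated correlation), with Cs at -0.29 ± 0.11 (log2 fold change, SE); no member passed, even adjusted over the list alone. The respiratory chain list was likewise below 0 in all 24 members (median -0.19; camera adjusted p = 1.83e-05, adjusted p = 0.425 with an estimated correlation), with Atp5a1 at -0.20 ± 0.09 and Atp5b at -0.21 ± 0.10. By exact permutation of list levels the adjusted p was 0.0308 for the TCA cycle (0.0529 with z scores, not past the threshold) and 0.0866 for the respiratory chain. Knockout replicate 4 lay above control replicate 4 on both lists, at a mean log2 CPM of 7.53 against 7.44 and 7.35 against 7.19. The glycolysis list was higher by camera, though fewer than 1 in 2 members passed: 9 of 22 were higher and 1 lower when adjusted over the list alone, and the median was 0.21 (camera adjusted p = 0.000139, adjusted p = 0.396 with an estimated correlation). The smallest p in that list belonged to Slc16a3 (0.89 ± 0.20), a lactate exporter, and Pfkfb3 (1.28 ± 0.30), which drives phosphofructokinase. Gapdh stood at 0.29 ± 0.10 and Ldha at 0.15 ± 0.09, and the glycolysis level passed by exact permutation (adjusted p = 0.0308) but not with z scores (adjusted p = 0.0960). In the gluconeogenesis list 10 of 11 members were below 0 (median -0.20; camera adjusted p = 0.000915, adjusted p = 0.244 with an estimated correlation). Without Pck1, a setting chosen after seeing the data because its deletion fixes part of that result, 9 of 10 were below 0 (median -0.16; camera adjusted p = 0.0158, adjusted p = 0.396 with an estimated correlation). The level without Pck1 was 0.24 lower on the log2 scale (exact permutation, adjusted p = 0.0435) and did not pass with z scores (adjusted p = 0.0960). The list's members lower over the list alone were Pck1 itself, Ppargc1a (-0.93 ± 0.26), a coactivator of mitochondrial and gluconeogenic genes, and pyruvate carboxylase Pcx (-0.40 ± 0.13). Fatty acid oxidation and ketogenesis did not pass (median -0.11; camera adjusted p = 0.0568), though it passed camera in 9 of 25 other settings, with medians from -0.32 to -0.06. Pentose phosphate and serine synthesis did not pass either (camera adjusted p = 0.843; median -0.03, with a mean of 0.05 and a camera direction of the other sign), with Tkt at -0.16 ± 0.12 and Pgd at -0.05 ± 0.10.

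Inflammatory genes were higher in the knockout colon as groups. Over all tested genes, 0 members of the cytokine, chemokine, neutrophil, monocyte and macrophage, and antimicrobial lists were higher, and Cx3cl1 was lower. Of 15 measured cytokine genes, 11 were higher when adjusted over the list alone, with a median log2 fold change of 1.76. The cytokine median ran from 0.89 to 2.13 over 25 other settings. Il1a (2.54 ± 0.52, SE), Il10 (1.76 ± 0.41), Il11 (1.99 ± 0.52) and Il1b (1.76 ± 0.47) had the smallest p, while Il18 stood at -0.30 ± 0.23. Of 16 chemokine genes 10 were higher and 2 lower over the list alone (median 1.62). Cxcl3 (3.52 ± 0.70), a neutrophil attractant, and Ccl4 (2.60 ± 0.55) and Ccl3 (2.72 ± 0.59), attractants of monocytes and lymphocytes, had the smallest p after Cx3cl1, which fell. The neutrophil list was above 0 in 16 of 16 members, 11 of them higher over the list alone, with a median of 1.76. The granule protein gene Ngp (6.06 ± 1.38), Clec4e (2.07 ± 0.52) and Il1r2 (2.34 ± 0.61) led it, S100a9 was 174 ± 146 against 49.7 ± 59.9 CPM (knockout against control, SD, n = 6), and Ly6g stood at 0.75 ± 0.34. Of 18 monocyte and macrophage genes 12 were higher and 1 lower over the list alone (median 0.55). Chil3 (3.78 ± 0.70) and Cd14 (1.25 ± 0.25) were among the higher genes, C1qb stood at 0.44 ± 0.14 and Lyz2 at 0.30 ± 0.18, and the fractalkine receptor gene Cx3cr1 was the lower one (-0.63 ± 0.13). Epithelial antimicrobial genes were partly higher, 6 of 15 over the list alone (median 0.41), led by Lcn2 (3.01 ± 0.70), Saa3 (2.66 ± 0.67) and Nos2 (1.02 ± 0.27), whereas Pigr (-0.31 ± 0.15) and Lypd8 (-0.18 ± 0.15) did not pass.

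The camera test gave adjusted p values of 1.03e-06 for cytokines, 6.49e-06 for chemokines, 9.17e-09 for neutrophil, 2.36e-07 for monocyte and macrophage and 0.00234 for epithelial antimicrobial genes. Each of these 5 lists had an adjusted p = 0.244 with an estimated correlation. Exact permutation of the neutrophil list level gave p = 0.0195 (adjusted 0.0435, and 0.0565 with z scores, not past the threshold) for a difference of 1.89 on the log2 scale, with SDs of 1.16 and 1.09 (n = 6 each). For the antimicrobial list the exact permutation p was 0.0281, or 0.0594 adjusted. Individual mice differed widely in these lists. The neutrophil levels of knockout replicates 4, 5 and 6 were -0.27, -0.26 and 0.29 from the mean of all 12 libraries. Knockout replicates 1, 2 and 3 lay between 1.52 and 2.32. Control replicate 4 stood at 1.01, above knockout replicates 4, 5 and 6 and above the other controls at -1.98 to -0.41.

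**Figure D3:**
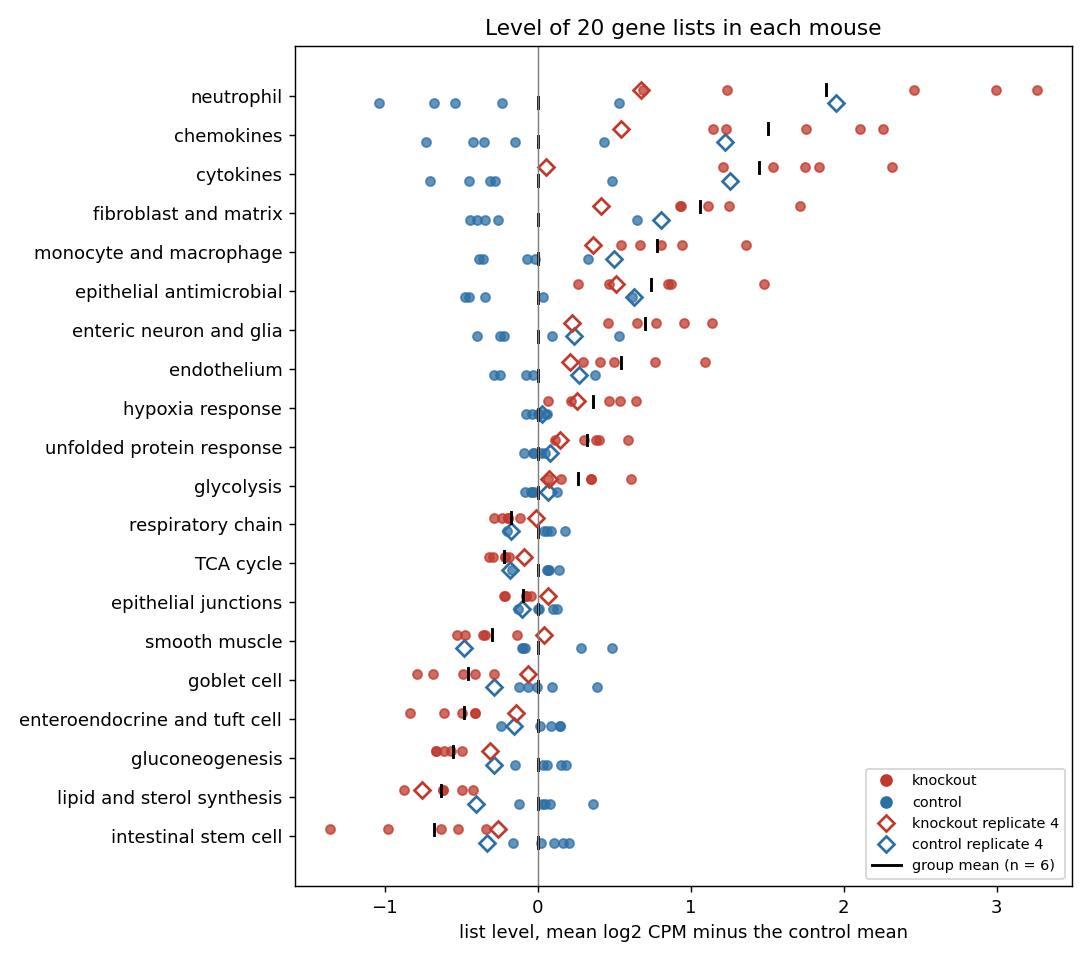
Level of 20 of the gene lists in each mouse, as mean log2 CPM of the list's members minus the mean of the 6 controls (horizontal axis), for knockout (red) and control (blue), with black ticks for group means. Knockout replicate 4 and control replicate 4 are drawn as open diamonds; on the neutrophil list the group means differ by 1.89 and knockout replicate 4 lies among the lowest of its group and control replicate 4 is the highest of its own.

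Stromal gene groups did not move together. Of 20 fibroblast and matrix genes 16 were higher over the list alone (median 0.83), among them Tnc (1.32 ± 0.26, SE), a matrix protein of healing tissue, Col4a1 (1.16 ± 0.28) and the matrix metalloproteinase gene Mmp10 (2.18 ± 0.55). Decorin (Dcn) was 1261 ± 365 against 605 ± 293 CPM (knockout against control, SD, n = 6) and Col3a1 stood at 0.79 ± 0.27. Enteric neuron and glia genes were higher in 9 of 14 over the list alone (median 0.70), with Vip at 1.25 ± 0.23, Tubb3 at 1.16 ± 0.24, the glial filament gene Gfap at 1.09 ± 0.26 and Nos1 at 0.73 ± 0.23. Endothelial genes were higher in 8 of 10 (median 0.59), with Vwf at 0.80 ± 0.19, Plvap at 0.67 ± 0.16 and Pecam1 at 0.60 ± 0.16. Smooth muscle genes were instead below 0 in 11 of 12 members (median -0.26), and Synpo2 (-0.79 ± 0.20) and Synm (-0.46 ± 0.13) were lower over the list alone, while Acta2 (-0.13 ± 0.15) and Tagln (-0.28 ± 0.17) did not pass. Camera adjusted p values were 1.07e-11, 1.16e-07 and 1.10e-06 for the 3 higher lists, each with adjusted p = 0.244 with an estimated correlation. For smooth muscle camera gave 0.00867, and adjusted p = 0.533 with an estimated correlation. The smooth muscle median ran from -0.35 to -0.14 over 25 other settings. The exact permutation test of list levels passed for the 3 higher lists (adjusted p 0.0308 for each) and not for smooth muscle (adjusted p = 0.192). On the fibroblast list knockout replicate 4 lay at -0.11 and control replicate 4 at 0.27 from the mean of all libraries.

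Lists of stem cell, goblet cell, and enteroendocrine and tuft cell genes were lower. Of 14 intestinal stem cell genes 9 were lower and 1, Cd44 (0.45 ± 0.15, SE), was higher over the list alone (median -0.62). Lgr5, the marker of crypt base stem cells, stood at -1.98 ± 0.58, Tnfrsf19 at -1.28 ± 0.28, Znrf3 at -0.56 ± 0.14 and Sox9 at -0.74 ± 0.19, all lower over the list alone, as was Lrig1 at -0.38 ± 0.15, whereas Prom1 stood at 0.27 ± 0.16. Goblet cell genes were below 0 in 16 of 16 members and lower over the list alone in 9 (median -0.45). Atoh1 (-0.69 ± 0.16), the secretory lineage factor, Ern2 (-0.64 ± 0.17) and Fcgbp (-0.45 ± 0.12) led the list, while Muc2 (-0.21 ± 0.17) and Zg16 (-0.32 ± 0.19) did not pass. Enteroendocrine and tuft cell genes were lower in 3 of 13 over the list alone, including Trpm5 (-1.10 ± 0.26) and Insl5 (-1.20 ± 0.34), and higher in 1, Dclk1 (0.51 ± 0.16), with a median of -0.53; Gcg and Chgb stood at -0.39 ± 0.18 and -0.24 ± 0.18. Camera adjusted p was 0.000188 for stem cell, 1.54e-06 for goblet cell and 0.00966 for enteroendocrine and tuft cell genes, each with adjusted p = 0.244 with an estimated correlation. Their list levels also differed by exact permutation, with adjusted p values of 0.0274, 0.0308 and 0.0274, though the last did not pass with z scores (exact permutation, adjusted p = 0.0565). On each of these lists knockout replicate 4 lay above control replicate 4. The mean log2 CPM was 4.65 against 4.58 for stem cell, 8.06 against 7.84 for goblet cell and 3.20 against 3.19 for enteroendocrine and tuft cell genes.

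The remaining epithelial lists passed camera but not the exact test of their levels. Absorptive colonocyte genes had a median of -0.12 (camera adjusted p = 0.0404, adjusted p = 0.565 with an estimated correlation), with Car1 at 0.12 ± 0.43 and Emp1 at 0.18 ± 0.14 (SE). Proliferation genes were below 0 in 19 of 20 (median -0.27; camera adjusted p = 0.0217, adjusted p = 0.642 with an estimated correlation), with Mki67 at -0.35 ± 0.38 and Top2a at -0.34 ± 0.32. Epithelial junction genes had a median of -0.14 (camera adjusted p = 0.0170, adjusted p = 0.486 with an estimated correlation), with Epcam at -0.22 ± 0.10 and Cdh1 at -0.20 ± 0.09. Only Cgn (-0.28 ± 0.08) and, in the higher direction, Cldn1 (1.15 ± 0.32) passed over that list alone. Detoxification genes had a median of -0.38 (camera adjusted p = 0.0230, adjusted p = 0.565 with an estimated correlation), with Gstm3 lower over the list alone (-0.96 ± 0.25) and Cyp2c55 and Ugt2b34 at -0.57 ± 0.45 and -0.56 ± 0.25. Genes of the regenerative epithelium were higher in 4 of 13 over the list alone, among them the growth factor gene Ereg (1.80 ± 0.51) and Plaur (1.21 ± 0.29), with Ly6a at 0.13 ± 0.21 and Anxa1 at 0.36 ± 0.17. That list had a median of 0.27 (camera adjusted p = 0.0133, adjusted p = 0.396 with an estimated correlation). The exact permutation test of list levels gave these 5 lists adjusted p values from 0.115 for regenerative epithelium to 0.406 for proliferation. Over 25 other settings of scaling, filter, test, design and libraries the camera call was kept in 16 for absorptive colonocyte, 19 for proliferation, 21 for detoxification, 23 for epithelial junction and 24 for regenerative epithelium genes. The proliferation median ran from -0.42 to -0.09 over these settings, with a camera adjusted p of up to 0.628.

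Stress response genes were modestly higher. Of 12 hypoxia response genes 5 were higher over the list alone (median 0.33), including P4ha1 (0.94 ± 0.21, SE) and Bnip3 (0.62 ± 0.17), while Hif1a (0.33 ± 0.23) and Ndrg1 (0.29 ± 0.20) did not pass. Of 14 unfolded protein response genes 5 were higher over the list alone (median 0.34), among them Ddit3 (0.46 ± 0.12) and the chaperone gene Hspa5 (0.59 ± 0.19), with Hsp90b1 at 0.14 ± 0.25. Camera adjusted p was 0.000218 for hypoxia and 0.000244 for the unfolded protein response, each with adjusted p = 0.244 with an estimated correlation. Both list levels separated the groups by exact permutation (adjusted p = 0.0206 each). In the glutathione and ferroptosis list 6 genes were higher and 3 lower of 16 over the list alone, and camera gave an adjusted p of 0.114 (past the threshold in 2 of 25 other settings) while the mean level was 0.31 higher (exact permutation, adjusted p = 0.0274); with z scores that level did not pass (adjusted p = 0.356). The higher members included Hmox1, the ferritin gene Fth1 (0.84 ± 0.20) and the cystine transporter gene Slc7a11 (1.47 ± 0.35), the lower ones included Nqo1 (-0.74 ± 0.20), and Ftl1 stood at 0.08 ± 0.12. Early response genes were higher in 4 of 12 over the list alone (median 0.48; camera adjusted p = 0.0133, adjusted p = 0.425 with an estimated correlation), including Ier3 (1.34 ± 0.26) and Junb (0.45 ± 0.15), with Jun at 0.19 ± 0.09; their level did not pass the exact test (adjusted p = 0.261).

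Lymphocyte and interferon lists did not pass, whereas MHC class II genes were lower by camera. T and NK cell genes had a median of -0.18 (camera adjusted p = 0.919), with Cd4 at -0.06 ± 0.21 and Gzmb at 0.38 ± 0.17 (SE); Foxp3 was the member higher over the list alone (0.97 ± 0.26). B and plasma cell genes had a median of -0.12 (camera adjusted p = 0.168, past the threshold in 4 of 25 other settings), with Igha at -0.03 ± 0.18 and Igkc at 0.01 ± 0.20. The interferon response list had a median of 0.07, a list level difference of -0.02 and a camera adjusted p of 0.987, with Iigp1 at 0.46 ± 0.48. MHC class II presentation genes were below 0 in 10 of 12 (median -0.41; camera adjusted p = 0.0217, adjusted p = 0.534 with an estimated correlation). There H2-Aa was among the 4 lower over the list alone (-0.51 ± 0.17), Cd74 stood at -0.39 ± 0.18, and the costimulatory genes Cd86 (0.61 ± 0.20) and Cd80 were higher over the list alone. Exact permutation of the MHC class II level gave an adjusted p of 0.370, and the camera call was kept in 22 of 25 other settings.

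Of the lists for blood and neighbouring tissues, erythrocyte genes alone passed camera, and no list level passed the exact permutation test. That call was kept in only 15 of 25 other settings, with a camera adjusted p of up to 0.213. Erythrocyte genes had a median of 0.91 (camera adjusted p = 0.0404, adjusted p = 0.533 with an estimated correlation; exact permutation, adjusted p = 0.308), with control replicate 6 the highest of the controls and Hbb-bs and Hba-a2, whose reads can be shared with a near-identical copy, at 0.91 ± 0.47 and 0.86 ± 0.47 (SE). Adipocyte genes, of interest since fat also makes Pck1, had a median of -0.17 (camera adjusted p = 0.0988, past the threshold in 6 of 25 other settings), with Fabp4 at 0.79 ± 0.33 and Pparg at -0.32 ± 0.13. The squamous epithelium list had 3 measured genes and did not pass (camera adjusted p = 0.470), with Dsg3 at 0.23 ± 0.43, while Sbsn, 1.94 ± 0.815 against 0.962 ± 0.484 CPM (SD, n = 6), was higher over the list alone. Neither did the distal colon list (camera adjusted p = 0.741; median 0.01, with a mean of -0.13 of the other sign), with Cldn8 at 0.35 ± 0.24 and Hoxb13 at -1.12 ± 0.51. The list of proximal colon and small intestine had a camera adjusted p of 0.413, with Aqp4 at -0.29 ± 0.26. Exocrine pancreas genes had a median of -2.62, varied widely between mice and did not pass (camera adjusted p = 0.272; exact permutation of its level, adjusted p = 0.647). Amy2a5, a pancreatic amylase gene with near-identical copies, was 236 ± 302 against 1650.2 ± 3139 CPM (knockout against control, SD, n = 6), and Ctrb1 stood at -2.03 ± 1.53. That median rested largely on control replicate 6, which held 7982 CPM of Amy2a5: without it the pancreas list had a median of -0.36. Over 25 other settings the median ran from -2.89 to 0.01, the latter with the pancreas level itself as a covariate, and 3 passed camera.

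Among the most variable genes, pancreatic RNA and not the genotype made the largest difference between libraries. The first principal component of the 500 most variable genes held 39.9% of the variance, was led by amylase, trypsin and lipase genes such as Pnlip and Prss2, and did not differ between the groups (knockout -1.24 ± 20.9, control 1.24 ± 26.7, SD, n = 6; exact permutation p = 0.866). The pancreas list level ran from -5.82 in control replicate 1 to 6.0 in control replicate 6 on the log2 scale, relative to the mean of all libraries. The second component held 29.8% of the variance and did differ (knockout 14.8 ± 14.3, control -14.8 ± 11.3; exact permutation p = 0.00649). Its high end was led by Ngp, Csf3, Chil3, Mmp8, Cxcl3 and Lcn2, and its low end held, among others, Pck1, Lgr5 and the distal colon gene Hoxb13. The first component of all tested genes did differ, by -48.0 (exact permutation p = 0.00649). That of the 500 most variable genes depended on single mice, with a group difference of -26.2 without control replicate 1 (exact permutation p = 0.0455) and 23.7 without control replicate 6 (exact permutation p = 0.0671).

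**Figure D4:**
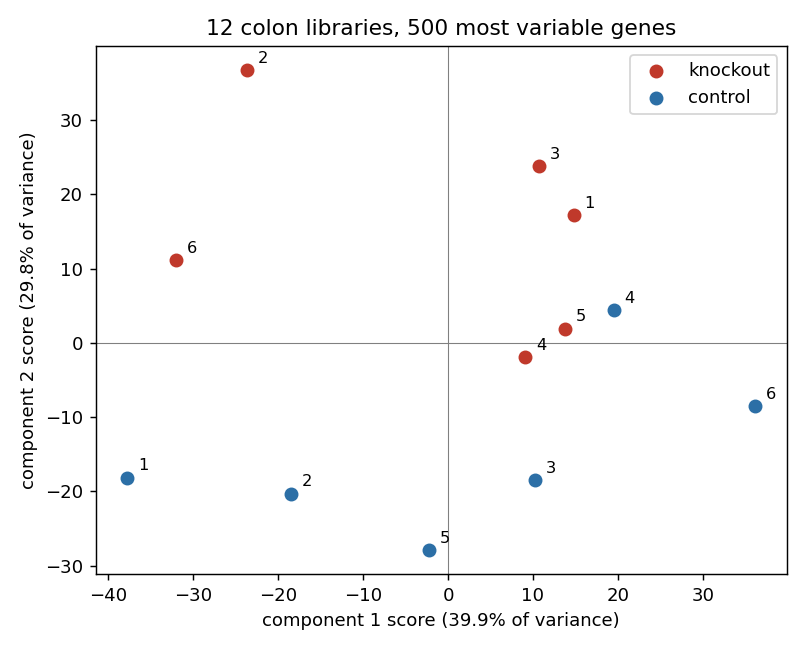
Scores of the 12 libraries on the first 2 principal components of log2 CPM, for knockout (red) and control (blue), each point numbered by its replicate. Component 1 (39.9% of the variance, horizontal axis) does not separate the groups; on component 2 (29.8%, vertical axis) the knockout mice lie higher, except that control replicate 4 lies at 4.43, above knockout replicates 4 and 5 at -1.93 and 1.90.

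The authors' deposited table reported many more genes than the 8 called here. It listed 1391 genes with an adjusted p under 0.05, 1019 of them higher and 372 lower in the knockout, and included all 8. Of 16 lipid and sterol synthesis genes, 12 were lower in the authors' deposited table, and 13 of 20 fibroblast and matrix genes, 8 of 15 cytokine genes, 7 of 16 neutrophil genes and 8 of 14 enteric neuron and glia genes were higher. The authors' deposited table also had 7 of 14 intestinal stem cell genes and 6 of 16 goblet cell genes lower. For MHC class II presentation it had 2 of 12 genes higher and 0 lower, adjusted over all its genes. Here 0 passed in either direction over all tested genes, and 2 higher and 4 lower passed over the list alone. The deposited log2 fold changes of H2-Aa (-0.44) and Cd74 (-0.31) were below 0, as they were here. Some lists past camera here held few genes under 0.05 there. These were 1 of 16 TCA cycle, 1 of 24 respiratory chain and 0 of 5 erythrocyte genes. No interferon response, proliferation or absorptive colonocyte gene was under 0.05 in the authors' deposited table. The p-values in the authors' deposited table equalled those of DESeq2's Wald test within 1% for 18130 of 18130 genes with a p.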

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

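The tests of an exchange of replicates 4 and of a lower share of epithelial cells were chosen after the levels they weigh had been seen. In the control group, replicate 6 had an erythrocyte list level of 6.15 (mean log2 CPM), far above the other 5 controls at 4.23 to 4.88; it was the only one of 120 groups examined in which a single mouse stood so far apart, where chance gives about 6.

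The 8 genes past the threshold were set against other splits of the same 12 libraries. Of 100 splits of 6 against 6, the real one included, 2 called as many genes, fewer than the 0.05 level allows for a random grouping. The 8 include the deleted Pck1, and the other splits carry the genotype difference within their groups, so chance is not excluded for each gene. The other of the 2 splits called 2117 genes, against 8 in the real one, and the next highest called 1. That split exchanges knockout replicate 4 and control replicate 4, which points to a structure of the samples beside the genotype. For the 27 lists past the camera threshold, 2 of 100 splits gave as many, the other 99 gave a median of 15, and the highest of these gave 28; it too exchanges both replicates 4, along with knockout replicate 5 and control replicate 2.

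The inflammatory and stromal lists were higher in the knockout, with knockout replicate 4 low and control replicate 4 high. Exchanged labels are argued against by Pck1 itself, whose CPM in knockout replicate 4 was 0.183 of that in control replicate 4. For a lower share of epithelial cells, the fibroblast and smooth muscle lists were compared, on the premise that both would rise alike. The fibroblast minus smooth muscle level differed between the groups by 1.36 (SDs 0.52 and 0.84, exact permutation p = 0.0173). That difference cannot decide the question, since stroma and muscle need not rise alike when epithelium is lost. Pancreatic RNA is argued against as well, since with the pancreas level as a covariate the neutrophil median log2 fold change went from 1.76 to 1.99, 1.13 times its value without. What stays open is the genotype itself, as a hypothesis of more severe injury without Pck1, and any untested difference between mice in the DSS taken. A lower share of epithelial cells stays open as well.

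The lipid and sterol synthesis list was lower in the knockout without overlap between the groups. It fell below the epithelial junction list by -0.54 (SDs 0.24 and 0.17, exact permutation p = 0.00433), which argues against an even loss of epithelial cells as the whole source. Its level differed by -0.63, against -0.68 for stem cell, -0.45 for goblet cell and -0.18 for absorptive colonocyte genes. A loss of particular epithelial cells therefore stays open. Pancreatic RNA is argued against too, since the median went from -0.64 to -0.69 with the pancreas level as a covariate, 1.07 times its value. With the neutrophil level as a covariate the median was -0.33, 0.517 of its value, between the bounds set in advance, so a direct effect of Pck1 loss and one that follows the degree of inflammation cannot be told apart. In that fit the list still passed camera at the preset correlation (adjusted p = 1.30e-11), while Pck1 was the 1 gene called (-3.31, edgeR adjusted p = 0.0273). Of the other 7 calls made without that covariate, the log2 fold change went from -1.03 to -0.87 for Hmgcs1 (SE 0.12 and 0.17), -0.86 to -0.79 for Lss, -0.59 to -0.56 for Cx3cl1, 0.55 to 0.49 for Pnrc1, 0.75 to 0.47 for Gpat3, 2.24 to 1.495 for Zbtb16 and 2.66 to 1.61 for Dio2.

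DESeq2 called 1511 genes where edgeR's quasi-likelihood test called 8. Over 40 splits that mix the genotypes evenly the median number of DESeq2 calls was 1. The highest such split called 175 genes with DESeq2, and edgeR called at most 3 in these splits. A structure between mice need show only in splits that follow it, and even mixing breaks up one partly aligned with the genotype. Calls made on differences between mice of one genotype therefore stay open. Low power of the quasi-likelihood test remains open too. It called 74% of genes simulated with a 2-fold change, between the bounds set in advance, and DESeq2 called 81%. The simulation changed 200 genes with noise drawn gene by gene, so it held no mice that stand apart and cannot decide the question. Low power cannot be told apart from a stricter treatment of the spread between mice. In the same simulation DESeq2 called 52 unchanged genes and edgeR 15.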

How the results depend on the processing

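The covariate, threshold, robust, likelihood ratio and TPM settings and the second component were chosen after seeing the data. The Pck1 log2 fold change kept its call under all 27 alternatives (-3.88 to -3.47 over the libraries left out), and Hmgcs1 kept its own in 26 of 27 (log2 fold change -1.11 to -0.94). The counts of calls did not hold: in place of 4 higher and 4 lower genes, DESeq2 size factors gave 33 and 19, library size only 230 and 45, DESeq2's test 1095 and 416, voom 30 and 19, voom with quality weights 1549 and 1339, a surrogate variable 48 and 45, a log2 fold change of at least 1 gave 2 and 2, the pancreas covariate 66 and 54, a threshold of 0.1 gave 949 and 435, robust estimation 32 and 21, the likelihood ratio test 858 and 302, log2(TPM + 1) 337 and 48, and log2(TPM + 0.1) 333 and 48. All 8 calls were kept in these fits, apart from the fold change minimum, which keeps 4 by construction. With upper quartile scaling or no filter 7 of 8 were kept. Leaving out 1 library gave 0 to 870 higher and 2 to 402 lower genes: 870 and 402 without knockout replicate 4, 728 and 279 without control replicate 4, 272 and 101 without control replicate 6, and 0 higher with 2 or 3 lower otherwise (edgeR, 2536 to 3093 unadjusted). All 8 calls were kept in those 3 fits, and only Pck1 and Hmgcs1 in the other 9. Over all 27 alternatives Dio2, Zbtb16, Pnrc1, Gpat3 and Cx3cl1 kept their call in 17 and Lss in 15. The cause was not tested, beyond the 380 genes with an adjusted p under 0.06.

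The numbers of the mice do not pair them: same-numbered mice deviated together with correlations of -0.50 to 0.08, and 0 of 6 correlated best with their own number. With the replicate number as a block 0 genes were higher and 1, Pck1 (-3.72, adjusted p = 0.0161), was lower in edgeR, with 2168 at an unadjusted p under 0.05. Of 38 lists, camera called 27, and 0 with an estimated correlation and 16 by fry; the level test called 17, and 10 with z scores, which lost gluconeogenesis, glycolysis, TCA cycle, glutathione, enteroendocrine, chemokine and neutrophil lists. The interferon list, not called, had a median of 0.07 and passed in the other direction at -0.33 (camera adjusted p = 0.0321) without knockout replicate 5; over the libraries left out the median ran from -0.33 to 0.27 and the adjusted p up to 0.999. The first component differed by -2.48 between the groups, by -48.0 with all tested genes (exact permutation p = 0.00649), and by -26.2 (without control replicate 1) to 23.7 (without control replicate 6) over the libraries left out; the second component differed by 29.6. The sex covariate and the FPKM setting were not run, since all libraries hold Y-linked reads and the table holds TPM.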

Other observations

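Pathways of the deposited annotation, tested after seeing the data, share some genes with the fixed lists, so they are not independent of them. Of 321 pathways with 10 to 300 tested genes, camera called 68 higher and 48 lower in the knockout; none passed with an estimated correlation (smallest adjusted p = 0.564) or by exact permutation of its level (smallest adjusted p = 0.0857). Complement and coagulation genes led, with 49 of 54 above 0 and a median log2 fold change of 0.68 (camera adjusted p = 5.21e-14). ECM-receptor interaction followed with 63 of 75 above 0 (median 0.42; camera adjusted p = 3.29e-09). On the lower side, steroid biosynthesis had 16 of 18 below 0 (median -0.58; camera adjusted p = 1.11e-06). Butanoate metabolism, the use of a main fuel of colonocytes, had 17 of 20 below 0 (median -0.37; camera adjusted p = 2.46e-05), and 1 of its genes, Hmgcs1, was called. Valine, leucine and isoleucine degradation had 37 of 48 below 0 (median -0.23), and propanoate metabolism 24 of 29 (median -0.26). DNA replication had 32 of 35 below 0 (median -0.28) and mismatch repair 21 of 22 (median -0.30), with exact permutation p values of 0.119 and 0.0628 before adjustment. The glycolysis and gluconeogenesis pathway was not higher, with 27 of 50 below 0 (median -0.03, camera adjusted p = 0.351). By its name it joins both routes, whose fixed lists went opposite ways, so it does not bear on glycolysis alone.

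Some genes, singled out after their values were seen, fell into 2 levels that did not follow the genotype in every mouse. Wdfy1 stood at 31.9 CPM in knockout replicate 2, 33.8 in knockout replicate 6, 38.0 in control replicate 1 and 35.5 in control replicate 4, and between 7.76 and 10.4 CPM in the other 8 mice. The spread within each level was at most 0.42 on the log2 scale. Ccl2, a monocyte attractant, instead followed the genotype apart from both replicates 4. It was at 26.2 to 62.2 CPM in 5 knockout mice and at 44.5 CPM in control replicate 4. Knockout replicate 4 held 9.45 CPM and the other controls 3.96 to 8.41 CPM. The Ccl2 levels were less distinct, with a spread within a level of up to 1.24 against a gap of 1.46 on the log2 scale.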
